A study of Mus musculus with 9 samples.

How the data were processed

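Poly(A) RNA of RAW264.7 cells was sequenced in 9 libraries, 3 each of untreated cells, cells given LPS and cells given LPS with an extract. Replicates were not said to be separate cultures. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9 and aligned with HISAT2 2.2.1, transcripts were assembled with StringTie 2.1.6, and DESeq2 and edgeR were used without stated versions. The counts in the deposited table are whole numbers per gene and library as the authors made them, and the labels state neither the counting tool nor the strand setting. The FPKM values in the deposited table are, per the file headers, fragments per kilobase and total fragments made by the authors. The genome build is not given in the sources used here, but start and end equalled those of GENCODE M21 on GRCm38 for 23547 of 26146 genes (90.1%). Since the strand setting is unknown, overlapping and antisense genes could not be told apart.

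Table columns were assigned to samples by the column name in each sample's label. The library names in the same labels give the opposite assignment of the LPS and LPS+Extract groups, so the groups are named after their columns, ET and M, and the exchanged assignment was run as an alternative. Total counts per library lay between 55039858 and 76242718. A gene with 0 counts was given a floor of 3 counts per library, or 0.0378 to 0.0555 CPM, and folds against a group at 0 are lower bounds from that floor. Floors and intervals cover counting error only. No fold is given for genes at or under the floor in one group and near it in the other.

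The design fixed before the data were examined foresaw limma on log2 FPKM. Because the table also held counts, the edgeR quasi-likelihood test on counts was used in its place, and the limma fit was kept as an alternative. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with FPKM of at least 1 in at least 3 of 9 libraries were tested (11536 genes), with TMM factors, 1 fit of the 3 groups and Benjamini-Hochberg adjustment at 0.05. The comparisons were ET with Normal, M with Normal, M with ET, and the mean of ET and M with Normal. Levels are TMM-scaled CPM, as mean ± SD of 3 libraries.

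Before the data were examined, 37 gene lists were fixed, of which 31 had at least 5 tested members. They were tested with camera at a preset inter-gene correlation of 0.01 and adjusted by Benjamini-Hochberg over lists, and again with the correlation estimated per list. Fry was run as another test. It asks whether list members changed at all, where camera asks whether they changed more than other genes. Counts and ranges over the alternatives of lists include fry and the estimated correlation. The lists cover inflammatory cytokines, chemokines, NF-kB targets, interferon-stimulated genes, immediate-early genes, nitric oxide, prostaglandin and itaconate enzymes, TLR4 signalling, pattern-recognition receptors, the inflammasome, alternative activation, MHC class I and II, osteoclast genes, NRF2, ATF4, unfolded protein, heat shock, p53, aryl hydrocarbon receptor, metal response, glycolysis, cholesterol, LXR, lysosome, autophagy, cell cycle, respiratory chain, mitochondrially encoded, ribosomal protein, ribosome biogenesis and macrophage identity genes. Marker lists of lymphocytes, fibroblasts, epithelial and endothelial cells, erythroid cells and platelets, and granulocytes were included. KEGG terms came from the deposited table and were tested with a hypergeometric test for terms of 10 to 500 members.

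Named genes followed a rule fixed in advance. It took a panel of 15 genes whether or not they passed, and the 6 largest rises and 6 largest falls of each comparison among called genes with no overlap between groups, mean FPKM of at least 5 in the higher group and no predicted name. It also took up to 4 members with the smallest p of each called list. List members named for going against their list, genes named for opposite directions and markers of other cells were chosen after their values were seen.

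Alternatives fixed in advance were other pseudocounts, filters, scalings and variance settings of the limma fit, a replicate block, fits of 6 libraries, stricter thresholds, other definitions of the response, exchanged labels and leaving out each library. Alternatives chosen after the data were seen were limma as designed, DESeq2, relative log expression factors, total counts only, a count filter, GC and length offsets, and protein-coding genes only. The fits were tested on simulated data with 200 changed genes among 11536. Between M and ET, edgeR recovered 47.8%, 80.6% and 92.4% of changes of 1.25, 1.5 and 2-fold, with 4.62% of calls false, and for ET with Normal 8.99% of calls were false. A simulated list of 30 shifted genes was called and an unshifted list was not. Simulated genes were drawn independently, so this does not test false list calls among correlated genes. Splice variants and sequence variants were not analysed here.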

Results

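Gene expression was measured by poly(A) RNA sequencing in 9 libraries of RAW264.7 cells, a mouse macrophage line. There were 3 libraries of untreated cells (Normal), 3 of cells given lipopolysaccharide (LPS), a bacterial cell wall component sensed by Toll-like receptor 4, and 3 of cells given LPS plus a Traditional Chinese Medicine extract. The labels used here state no plant, dose or exposure time. They also conflict on the treated groups. Samples titled LPS point to table columns named ET but carry the library name M. Samples titled LPS+Extract point to columns named M but carry the library name ET. The groups are therefore called the ET libraries and the M libraries. By the column names, ET is LPS alone and M is LPS with extract. By the library names, M is LPS alone and ET is LPS with extract. The expression values were not used to choose between these readings. The series' own design text calls the LPS group a model and does not say what M or ET stands for. Total counts were 56921531 to 76242718 in the Normal libraries, 55039858 to 62962615 in ET and 57796361 to 60881764 in M. A floor of 3 counts per library, used for genes at 0, stood for 0.0378 to 0.0555 CPM (TMM-scaled counts per 1e6 counts). The leading principal component carried 90.5% of the variance and set Normal apart from both treated groups. The next carried 2.28% and set ET apart from M, with ET replicate 3 nearer to M (7.22, against 14.7 and 17.1 for ET replicates 1 and 2 and -13.7 to -11.5 for M). Its chi-square per gene was 26.3 and 21.6 against the other ET libraries, which gave 14.6 between themselves.

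The contrast of both treated groups with Normal asks what LPS did with or without the extract, and it is the same under both readings of the labels. Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254, GRCm38), had 0 counts in all 3 Normal libraries. It reached 319.9 ± 11.7 CPM in ET and 331 ± 12.7 CPM in M (SD, n = 3), at least 6284-fold and 6494-fold higher. Il6, a pyrogenic cytokine with 0 counts in Normal, reached 199 ± 26.9 CPM in ET and 340.3 ± 26.1 CPM in M, at least 3911-fold and 6685-fold higher. Il1b (chromosome 2, 129364570 to 129371139), another fever-inducing cytokine, went from 0.499 ± 0.037 CPM in Normal to 404 ± 27.3 in ET and 725 ± 41.3 in M. Ptgs2, the inducible cyclooxygenase, went from 1.28 ± 0.125 to 999.6 ± 72.4 and 1697 ± 173. Tnf rose from 61.7 ± 5.59 CPM to 589 ± 20.4 in ET and 460 ± 27.0 in M, and Acod1, which makes itaconate, from 8.95 ± 0.943 to 1188 ± 78.4 and 1364 ± 59.5. For each gene named with levels in this contrast, every treated library lay on the same side of every Normal library. For list members the choice by smallest p favours this. Of 11536 genes tested, 4241 were higher and 4242 lower in the treated mean (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 1221 and 585 of them by at least 2-fold. The even split rests on the scaling, since total counts without TMM factors gave 3609 higher and 5042 lower, limma on log2 FPKM 3632 and 5030, and limma with quantile normalization 3486 and 5183.

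**Figure D1:**
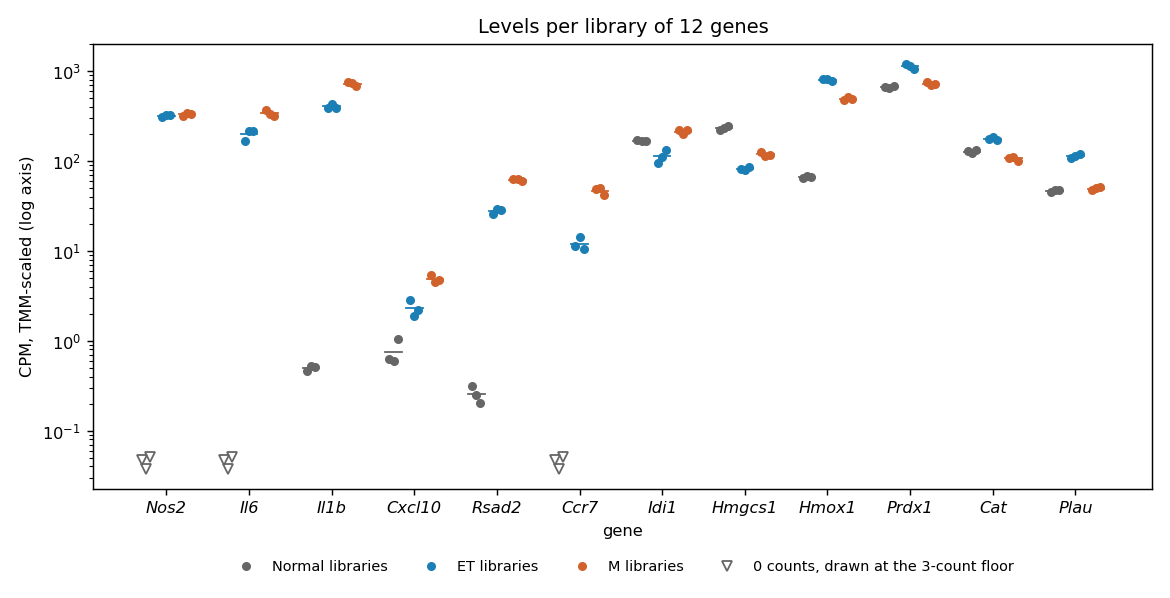
Levels of 12 genes in each library, as TMM-scaled CPM on a log axis, with points for single libraries of the Normal, ET and M groups and short lines for means of 3 libraries; open triangles mark libraries with 0 counts at their 3-count floor. Il1b lay between 0.458 and 0.529 CPM in Normal, between 387 and 435 CPM in ET and between 678 and 756 CPM in M.

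Secreted inflammatory mediators rose together. Of 20 inflammatory cytokine genes in the data 16 were tested, of which 14 rose, 1 (Tnfsf9) fell and 1 did not pass. Their median log2 change was 7.22, or 5.86 with the 5 members at 0 counts in Normal set to their bound. All 12 tested chemokine genes rose, of 18 in the data (median 7.43). Genes at 0 counts in Normal passed the filter only through treated libraries, which favours rises in these counts and medians. Ccl2, which attracts monocytes, went from 0.230 ± 0.0949 CPM to 320.2 ± 15.8 in ET and 288 ± 12.8 in M, and Ccl3, from 57.2 ± 4.05 to 2928 ± 180 and 2435 ± 86.9. All 40 tested type I interferon-stimulated genes rose, of 45 in the data (median 4.37). Irf7, a transcription factor of the interferon response, went from 4.69 ± 0.478 to 392 ± 11.9 and 488 ± 12.4 CPM. Of 27 NF-kB feedback genes and targets, 24 rose and 3 did not pass (median 1.69). Of 23 immediate-early and AP-1 genes 22 rose and 1 (Btg2) fell (median 2.43). Camera gave Benjamini-Hochberg adjusted p = 7.54e-29 for the cytokines, 1.24e-43 for the chemokines, 3.19e-68 for the interferon-stimulated genes, 2.48e-24 for the NF-kB list and 1.83e-17 for the immediate-early list. The same lists had camera adjusted p = 0.00391, 0.011, 0.00386, 0.0184 and 0.00391 with an estimated correlation (Benjamini-Hochberg).

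Antigen presentation and surface receptors moved too. Of 21 MHC class I presentation genes, 16 rose, 2 fell and 3 did not pass (median log2 change 1.13). Of 10 MHC class II and co-stimulation genes 7 rose and 3 fell (median 3.01). Cd274, the ligand PD-L1, went from 2.52 ± 0.186 CPM to 39.8 ± 3.01 in ET and 52.5 ± 1.54 in M. H2-D1, a class I heavy chain, went from 146 ± 3.22 to 568 ± 15.8 and 593 ± 11.2, with the limit that reads of the H2 genes can be split among close copies. Of 20 other pattern-recognition and scavenger receptors, 15 rose and 4 fell (median 1.80). Cd36, a scavenger receptor, went from 2.03 ± 0.619 to 251 ± 12.5 and 305 ± 26.0 CPM. Among 10 osteoclast differentiation genes 9 rose and 1 did not pass (median 0.84). Acp5, the tartrate-resistant acid phosphatase, went from 3.53 ± 0.526 to 64.3 ± 4.84 and 66.05 ± 1.12 CPM. Among 11 anti-inflammatory and alternative-activation markers 9 rose and 2 fell (median 1.54). Il1rn, the interleukin-1 receptor antagonist, went from 2.86 ± 0.191 to 674 ± 51.2 and 703 ± 46.8 CPM. Trem2, a lipid-sensing receptor, fell from 205 ± 5.38 to 51.8 ± 1.40 and 37.1 ± 1.80. Camera adjusted p (Benjamini-Hochberg) was 1.52e-07 for class I, 5.86e-06 for class II, 2.34e-06 for the receptors, 6.26e-08 for the osteoclast list and 0.00177 for the alternative-activation list. Camera gave adjusted p = 0.0473, 0.0545, 0.0792, 0.0177 and 0.0473 with an estimated correlation (Benjamini-Hochberg), so that the class II and receptor calls were lost.

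Glycolysis, NRF2, metal response, lysosomal and p53 target genes rose in more members than fell. Of 32 glycolysis and HIF1 target genes 24 rose and 5 fell (median log2 change 0.58). The glucose transporter Slc2a1 stood at 104 ± 3.08 CPM in Normal, 321 ± 9.43 in ET and 330.1 ± 12.6 in M. Of 28 NRF2 antioxidant targets 17 rose and 8 fell (median 0.42). Among those that rose, Hmox1, the inducible heme oxygenase (chromosome 8, 75093621 to 75100589), went from 66.65 ± 1.29 CPM to 806 ± 19.4 in ET and 492 ± 16.5 in M. Of 16 metal response genes 11 rose and 3 fell (median 0.63). The metal transporter Slc11a1 stood at 31.35 ± 2.48, 304 ± 13.5 and 270.0 ± 15.4 CPM in Normal, ET and M. Of 35 lysosomal genes 22 rose and 12 fell (median 0.45). Of 27 p53 targets 20 rose and 5 fell (median 0.43), including the cell cycle inhibitor Cdkn1a, from 113 ± 6.26 to 400.4 ± 12.9 and 408 ± 22.6 CPM. Camera adjusted p (Benjamini-Hochberg) was 8.65e-06 for glycolysis, 9.28e-06 for NRF2 targets, 0.00131 for the metal list, 0.000751 for lysosome and 0.00973 for p53 targets. Camera gave adjusted p = 0.0612, 0.191, 0.0498, 0.466 and 0.191 with an estimated correlation (Benjamini-Hochberg), so that only the metal call held there.

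The 16 nitric oxide, prostaglandin and itaconate enzymes split, 7 up and 7 down with 2 not passing. Beside the rises of Nos2, Ptgs2 and Acod1, the constitutive cyclooxygenase Ptgs1 fell from 194 ± 6.96 to 54.3 ± 3.37 and 45.9 ± 1.49 CPM. Their median was -0.11, their mean 2.08 and the camera direction up (Benjamini-Hochberg adjusted p = 0.00453), with adjusted p = 0.191 with an estimated correlation. That call also ended in the limma fit with a pseudocount of 0.1 (Benjamini-Hochberg adjusted p = 0.711) and elsewhere among the alternatives, whose adjusted p ran from 2.35e-07 to 0.959. The limma fit of the design fixed in advance lost the call too.

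Genes of sterol synthesis, cell division and the protein synthesis machinery were mostly lower in treated cells. Of 25 cholesterol biosynthesis genes 22 fell and 2 rose (median log2 change -0.64). Hmgcs1, the cytosolic HMG-CoA synthase, fell from 233 ± 12.9 CPM to 81.9 ± 3.41 in ET and 119 ± 5.89 in M. Of 20 LXR targets 13 fell and 5 rose (median -0.55). Scd1, a fatty acid desaturase, fell from 475 ± 11.8 to 175 ± 2.60 and 186 ± 4.74 CPM. The sterol exporter Abca1 rose from 0.546 ± 0.150 to 28.6 ± 1.59 and 65.9 ± 8.46. Of 40 G1/S and replication genes 33 fell and 4 rose (median -0.43). Thymidine kinase, Tk1, stood at 251 ± 2.64, 98.1 ± 3.82 and 98.9 ± 4.19 CPM in Normal, ET and M. Of 42 G2/M and mitosis genes 36 fell and 2 rose (median -0.41). Of 78 cytosolic ribosomal protein genes 61 fell and none rose (median -0.21). Of 52 nuclear-encoded respiratory chain genes 35 fell and 3 rose (median -0.19), with Sdha, a succinate dehydrogenase subunit, at 345 ± 4.86, 244 ± 0.569 and 242 ± 1.72 CPM. Camera adjusted p (Benjamini-Hochberg) was 7.21e-08 for cholesterol, 0.00462 for LXR, 9.89e-06 for G1/S, 3.05e-06 for G2/M, 0.000944 for ribosomal proteins and 0.0103 for the respiratory chain. With an estimated correlation the adjusted p = 0.0473, 0.0498, 0.0678, 0.0524, 0.551 and 0.533 (camera, Benjamini-Hochberg), so that the last 4 calls were lost. The 13 mitochondrially encoded genes, of which 11 fell, were not called (median -0.30; camera Benjamini-Hochberg adjusted p = 0.0557). Leaving out Normal replicate 3, ET replicate 1, M replicate 1 or M replicate 3 brought a call (camera Benjamini-Hochberg adjusted p = 0.0425, 0.0407, 0.0363 and 0.0464), in a range of 0.000213 to 0.533 over all alternatives, 17 of 28 of which called the list. Mitochondrial transcripts made up 4.39 to 4.61% of counts in Normal, 3.29 to 3.62% in ET and 3.46 to 3.78% in M.

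The remaining lists were not called in this contrast with the fit used here. Members rose and fell in numbers of 15 and 9 of 28 for TLR4 signalling, 11 and 3 of 15 for the inflammasome, 10 and 2 of 18 for heat shock, 15 and 3 of 21 for the unfolded protein response, 17 and 6 of 25 for ATF4 targets and 17 and 5 of 26 for autophagy. Camera adjusted p (Benjamini-Hochberg) was 0.797, 0.237, 0.465, 0.379, 0.112 and 0.178 for these lists. Of 28 alternatives, however, 10 called the inflammasome, 10 the ATF4 targets, 10 autophagy and 8 the unfolded protein response, with adjusted p over all alternatives of 3.18e-06 to 0.454, 4.88e-06 to 0.533, 4.29e-08 to 0.238 and 7.74e-06 to 0.591 (Benjamini-Hochberg). The lowest value of each range came from fry, which does not compare members with other genes. With 73.5% of all tested genes called in this contrast, a fry call was likely for most lists. The limma fit of the design fixed in advance was among those that called each of these lists. It also called the mitochondrially encoded list. TLR4 signalling, heat shock and macrophage identity were each called in 1 of 28, which was fry. Of 36 ribosome biogenesis genes 13 rose and 14 fell, with a median of -0.02, a mean of 0.01 and camera pointing down (Benjamini-Hochberg adjusted p = 0.758). Of 17 macrophage identity genes 7 rose and 7 fell, with a median of -0.05, a mean of 0.67 and camera pointing up (Benjamini-Hochberg adjusted p = 0.465). The list of aryl hydrocarbon receptor targets had 3 tested members of 11 in the data. Tiparp and Arnt rose and Nfe2l2, the gene of NRF2 itself, fell by 1.17 on the log2 scale. Adjusted over the list alone, counts equalled those over all genes in this contrast except for the enzyme list (7 up, 8 down), G2/M (2 up, 37 down) and macrophage identity (7 up, 8 down). Among markers of other cell types, the immunoglobulin gene Ighm went from 468 CPM in Normal to 51.3 in ET and 60.8 in M. Lum, a fibroblast proteoglycan, went from 0 counts to 8.13 and 13.1 CPM.

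ET libraries were set against Normal, which asks for the effect of LPS alone by the column names and of LPS with extract by the library names. The 6 genes with the largest fitted rises all had 0 counts in Normal. Csf3, which drives granulocyte production, reached 669.9 ± 51.6 CPM (at least 13159-fold higher). The others were Nos2, Il6, Lcn2, an iron-sequestering lipocalin, at 224 ± 9.93 (at least 4408-fold), Upp1, a uridine phosphorylase, at 79.3 ± 3.95 (at least 1558-fold), and Cstdc4, of a multicopy cystatin family, at 71.8 ± 4.14 (at least 1410-fold). Among the largest falls were S1pr1, a sphingosine-1-phosphate receptor, from 25.4 ± 2.21 to 0.493 ± 0.171 CPM, and Cd101, from 18.9 ± 1.94 to 0.589 ± 0.263. Trp53i11, a p53-induced gene, went from 90.8 ± 2.04 to 3.87 ± 0.830. The immunoglobulin joining segments Ighj3 and Ighj4 went from 0.626 ± 0.0163 and 1.67 ± 0.0690 CPM to 0.00616 ± 0.0107 and 0.0738 ± 0.0241. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 4037 genes higher and 4066 lower, where total counts without TMM factors gave 3473 and 4770. In 8445 genes (73.2%) there was no overlap between the groups' libraries, where chance gives 10%. NRF2 targets stood at 18 up and 5 down of 28 (median log2 change 0.66; camera Benjamini-Hochberg adjusted p = 1.02e-08, and adjusted p = 0.104 with an estimated correlation). Cholesterol biosynthesis stood at 23 down and 2 up of 25 (median -0.77; camera Benjamini-Hochberg adjusted p = 8.70e-10, and 0.0305 with an estimated correlation). The ATF4 targets (17 up and 6 down of 25; camera Benjamini-Hochberg adjusted p = 0.0492, and adjusted p = 0.446 with an estimated correlation) were called here. Their call ended without Normal replicate 1 (0.0505), Normal replicate 2 (0.0554), ET replicate 1 (0.0663) or ET replicate 2 (0.0739), in a range of 3.85e-06 to 0.446 over the alternatives, 9 of 29 of which lost it. The 13 mitochondrially encoded genes (11 down, none up; median -0.35) were called here as well (camera Benjamini-Hochberg adjusted p = 0.0461, and adjusted p = 0.515 with an estimated correlation). That call ended without Normal replicate 1 (0.0535) or ET replicate 2 (0.0589), and in 5 of 29 alternatives in all (range 0.000255 to 0.515). In M against Normal the list was not called (camera Benjamini-Hochberg adjusted p = 0.0722), but it was without M replicate 1 (0.0373) and in 11 of 29 alternatives in all (range 0.000852 to 0.545). The difference itself, M against ET, was not called (0.512), but with the GC offset the list was called lower in M (camera Benjamini-Hochberg adjusted p = 0.0233).

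M libraries against Normal gave the effect of LPS with extract by the column names and of LPS alone by the library names. Csf3 reached 726 ± 40.4 CPM (at least 14262-fold higher) and Lcn2 259.6 ± 24.6 (at least 5100-fold). Upp1 reached 95.8 ± 8.20 (at least 1881-fold) and Il11, a cytokine of the interleukin-6 family, 81.3 ± 2.01 (at least 1597-fold), all from 0 counts. Among the largest falls, Cd101 went to 0.397 ± 0.185 CPM, and S1pr1 to 0.611 ± 0.253. Klhl30 went from 51.05 ± 3.32 to 2.90 ± 0.919 and Cd24a, a surface glycoprotein, from 17.7 ± 1.0 to 1.10 ± 0.135. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 4101 genes higher and 3978 lower. In 8628 genes (74.8%) there was no overlap, where chance gives 10%. The split was 3460 and 4757 with total counts without TMM factors, 3467 and 4755 with limma on log2 FPKM, and 3333 and 4888 with limma and quantile normalization. NRF2 targets stood at 15 up and 11 down of 28 (median log2 change 0.14; camera Benjamini-Hochberg adjusted p = 0.00116, and adjusted p = 0.339 with an estimated correlation). That NRF2 call was lost in 9 of 29 alternatives, with medians of 0.05 to 0.21 and adjusted p of 1.57e-06 to 0.339 (Benjamini-Hochberg). The limma fit of the design fixed in advance was among those that lost it. Cholesterol biosynthesis stood at 20 down and 3 up of 25 (median -0.56; camera Benjamini-Hochberg adjusted p = 2.76e-05, and adjusted p = 0.0677 with an estimated correlation).

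The 2 comparisons with Normal share their controls. Log2 changes of ET and M against Normal correlated with r = 0.987 across genes, which are not independent replicates. Simulated unchanged groups sharing the controls gave 0.496. The covariance was 2.32 against a simulated 0.0120. Both comparisons called 3685 genes higher and 3551 lower, where independent lists would share 1435 and 1402, and 13 genes went opposite ways. The simulated covariance is small beside the observed one, so the shared Normal libraries can give only a small part of the correlation. Their part in the excess of shared calls was not measured, since 3 libraries cannot be split into sets of 2 or more each.

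M libraries were then set against ET libraries, the comparison that isolates the extract. By the column names a higher value in M is higher with extract, and by the library names it is lower with extract. Cytokine, interferon-stimulated, MHC class II and sterol synthesis genes stood higher in M, and antioxidant genes lower. Il1b was 725 ± 41.3 CPM in M and 404 ± 27.3 in ET (SD, n = 3; log2 change 0.84), Il6 340.3 ± 26.1 and 199 ± 26.9 (0.77), Ptgs2 1697 ± 173 and 999.6 ± 72.4 (0.76), and Ccl5 203 ± 21.1 and 137 ± 17.1 (0.57). Tnf went the other way, at 460 ± 27.0 and 589 ± 20.4 (-0.36), and so did Hmox1, at 492 ± 16.5 and 806 ± 19.4 (-0.71). The edgeR quasi-likelihood test gave these 6 genes Benjamini-Hochberg adjusted p = 1.94e-06, 0.000598, 3.1e-05, 0.00287, 0.00323 and 6.48e-07, and in each all 3 M libraries lay beyond all 3 ET libraries. Ccl5 lost its call in limma with pseudocounts of 0.1 and 0.01 (Benjamini-Hochberg adjusted p = 0.0952 and 0.155), in a range of 0.000171 to 0.155.

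Other genes of the panel fixed in advance were less firm between M and ET. Cxcl10 (4.88 ± 0.424 and 2.33 ± 0.484 CPM; log2 change 1.06) and Nfkbia (283 ± 6.29 and 252 ± 8.41; 0.17), which encodes the NF-kB inhibitor, passed narrowly (edgeR, Benjamini-Hochberg adjusted p = 0.0117 and 0.0177). Cxcl10 did not pass without ET replicate 2 (0.0582) or M replicate 1 (0.0506), in a range of 0.000398 to 0.0582 over the alternatives. Nfkbia did not pass without ET replicate 1 (0.066), M replicate 1 (0.0524) or M replicate 2 (0.073), in a range of 0.00228 to 0.073. Nos2 (log2 change 0.05), Acod1 (0.20), Ccl2 (-0.15) and Il10 (-0.67, at 2.97 ± 0.114 and 4.71 ± 0.448 CPM) did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.542, 0.0611, 0.115 and 0.229). Leaving out Normal replicate 2 for Acod1 (0.0388), ET replicate 3 for Ccl2 (0.0286) or Normal replicate 1 for Il10 (0.033) brought them past the threshold, in ranges of 0.0104 to 0.184, 0.0217 to 0.643 and 0.00283 to 0.627. Nqo1, Arg1 and Mrc1 were below the filter, with at most 66, 11 and 19 counts in any library.

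Genes with the largest differences between M and ET included Ccr7, the receptor that guides cells to lymph nodes (chromosome 11, 99144196 to 99155077), at 46.6 ± 4.16 CPM in M and 11.97 ± 1.87 in ET. Il11 stood at 81.3 ± 2.01 and 21.95 ± 2.36, and Crhbp, which binds corticotropin-releasing hormone, at 50.4 ± 3.57 and 12.1 ± 0.704. Tgm2, a transglutaminase, stood at 64.5 ± 4.73 and 19.8 ± 1.68, Ramp3, a receptor activity-modifying protein, at 9.69 ± 0.432 and 2.08 ± 0.966 CPM, and Crispld2 at 39.3 ± 4.14 and 10.2 ± 2.70. Among genes lower in M was Ptgr1, which inactivates leukotrienes and prostaglandins (chromosome 4, 58965439 to 58987119), at 31.9 ± 2.36 and 81.3 ± 5.07 CPM. Plau, the urokinase, stood at 49.3 ± 1.82 and 113 ± 5.62, and Angptl2, an angiopoietin-like protein, at 72.0 ± 0.413 and 130.4 ± 3.64. Gpnmb, a lysosomal glycoprotein, stood at 447 ± 19.9 and 744 ± 58.5, and the reductases Cbr3, at 4.62 ± 0.306 and 8.82 ± 1.20, and Blvrb, at 18.2 ± 2.19 and 31.1 ± 1.62. Their log2 changes ran from 1.70 to 2.23 and from -1.35 to -0.74, and by the rule that chose them every library of one group lay beyond every library of the other. In all, 573 genes were higher and 475 lower in M of 11536 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 41 and 13 of them by at least 2-fold, with a median size of 0.28 on the log2 scale. The majority turned in some other scalings, to 461 higher and 552 lower with total counts without TMM factors, 407 and 473 with limma on log2 FPKM, and 448 and 528 with limma and quantile normalization. It stayed in others, with 51.4% of called genes higher in M with relative log expression factors, 51.0% with limma and median-of-ratios scaling, and 53.8% with limma on rescaled FPKM. Called or not, 3313 genes (28.7%) had no overlap between the groups, where chance gives 10%. Leaving out a single library moved these counts. Without ET replicates 1, 2 and 3 they were 265.0 and 284, 292 and 244, and 1121 and 707. Without M replicates 1, 2 and 3 they were 293 and 268, 368 and 313, and 290 and 247.

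Of the lists fixed in advance, 7 were called between M and ET with the preset and with an estimated correlation. Higher in M were 8 of 16 inflammatory cytokines (10 adjusted over the list alone), with only Tnf lower by both counts (median log2 change 0.56). Lif, a leukemia inhibitory factor, stood at 142 ± 6.65 and 47.0 ± 5.18 CPM and the alarmin Il33 at 15.8 ± 0.508 and 5.15 ± 0.929. So were 23 of 40 interferon-stimulated genes (37 adjusted over the list alone; none lower; median 0.37), with the antiviral enzyme Rsad2 at 61.9 ± 1.41 and 27.7 ± 1.71 CPM. Of 25 cholesterol biosynthesis genes 18 were higher and none lower (21 adjusted over the list alone; median 0.25), with Idi1, an isomerase of the isoprenoid path, at 212 ± 12.5 and 112 ± 19.0 CPM. Of 10 MHC class II and co-stimulation genes 6 were higher and none lower (7 adjusted over the list alone; median 0.39), with the maturation marker Cd83 at 385 ± 37.3 and 212 ± 13.8. In the unfolded protein response 9 of 21 were higher and none lower (15 adjusted over the list alone; median 0.15), with the chaperone Hspa5 at 2152 ± 3.27 and 1802 ± 62.9 CPM. Lower in M were 21 of 28 NRF2 targets, with none higher (24 lower and 1 higher adjusted over the list alone; median -0.35). Catalase, Cat, stood at 107 ± 5.18 and 176 ± 6.78 CPM and the peroxiredoxin Prdx1 at 725 ± 20.7 and 1128 ± 64.8. In the metal response list 5 of 16 were lower and 1, the hepcidin gene Hamp, higher (7 and 2 adjusted over the list alone; median -0.11). The iron exporter Slc40a1 stood at 7.67 ± 0.614 and 16.4 ± 0.741 CPM, and Hamp was low, at 2.25 ± 0.495 and 0.986 ± 0.125. The ferritin genes Fth1 and Ftl1 (log2 changes -0.36 and -0.54) are uncertain because pseudogenes can take their reads. Both belong to the NRF2 list as well, so the metal and NRF2 calls are not independent. Fth1 also lost its call under quantile normalization (limma, Benjamini-Hochberg adjusted p = 0.0878, the highest of a range from 6.85e-17). For each member named here all 3 M libraries lay beyond all 3 ET libraries, which the choice of members by smallest p favours. In the order cytokines, interferon-stimulated, cholesterol, class II, unfolded protein, NRF2 and metal lists, camera gave Benjamini-Hochberg adjusted p = 1.91e-17, 2.93e-33, 2.76e-23, 2.6e-12, 1.12e-07, 2.14e-42 and 7.88e-05. With an estimated correlation camera gave adjusted p = 0.00237, 0.00237, 0.0065, 0.011, 0.0327, 0.0108 and 0.0241 (Benjamini-Hochberg).

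**Figure D2:**
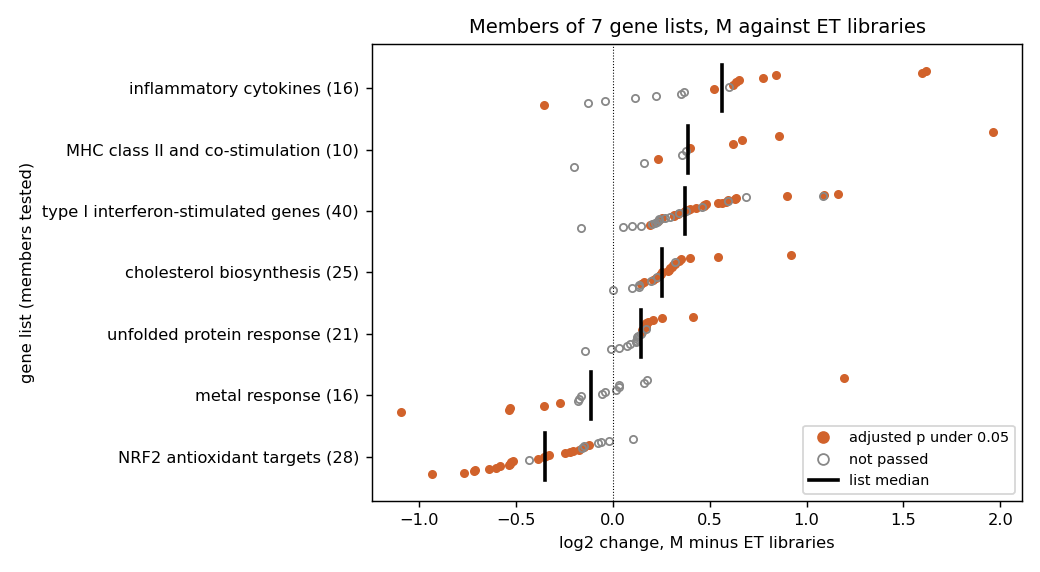
Log2 change of M minus ET libraries for each tested member of 7 gene lists (number of members in brackets); filled points passed the edgeR quasi-likelihood test, open points did not, and bars mark list medians. Medians ran from -0.35 for the NRF2 antioxidant targets to 0.56 for the inflammatory cytokines, and a value above 0 is higher with extract by the column names and lower with extract by the library names.

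Another 8 lists were called between M and ET with the preset correlation only. Calls that rest on it alone are weak. Other splits of the M and ET libraries, with at most 1 gene called, called up to 12 lists that way, against 15 for the real split. NF-kB genes were higher in M in 12 and lower in 1 of 27 (17 and 1 adjusted over the list alone; median log2 change 0.23). The subunit Rel stood at 172 ± 11.2 and 116 ± 6.75 CPM and Tnfaip2 lower, at 91.3 ± 3.96 and 119 ± 4.97. Chemokines were higher in 4 and lower in 2 of 12 (4 and 3 adjusted over the list alone; 0.10). Ccl22, which attracts T cells, stood at 1872 ± 144 and 738 ± 86.4 CPM, but DESeq2 did not call it (Benjamini-Hochberg adjusted p = 0.139, in a range of 7.90e-07 to 0.139). Immediate-early genes were higher in 7 and lower in 2 of 23 (7 and 5 adjusted over the list alone; 0.07), with the nuclear receptor Nr4a1 at 58.9 ± 2.62 and 27.8 ± 3.31. MHC class I genes were higher and lower in 5 and 1 of 21 (7 and 2 adjusted over the list alone; 0.13). Lysosomal genes were lower in M in 14 of 35 (19, with 1 higher, adjusted over the list alone; -0.12), with cathepsin B, Ctsb, at 2627 ± 71.9 and 3414 ± 229 CPM. ATF4 targets were lower in 8 and higher in 1 of 25 (11 and 1 adjusted over the list alone; -0.12), with the serine synthesis gene Phgdh at 340.0 ± 8.96 and 410.1 ± 19.2. G1/S genes were lower in 6 of 40 (14, with 1 higher, adjusted over the list alone; -0.09), with Rrm2, a ribonucleotide reductase subunit, at 292 ± 1.91 and 337 ± 9.73. G2/M genes were lower in 7 of 42 (11, with 1 higher, adjusted over the list alone; -0.05). Camera gave Benjamini-Hochberg adjusted p = 1.86e-10, 0.0264, 0.021, 0.0167, 1.94e-09, 5.59e-05, 0.00161 and 0.0264 in that order. Camera gave adjusted p = 0.0786, 0.411, 0.196, 0.225, 0.225, 0.196, 0.21 and 0.316 with an estimated correlation (Benjamini-Hochberg). Without ET replicate 3 the chemokine, immediate-early, class I and G2/M calls ended as well (camera Benjamini-Hochberg adjusted p = 0.289, 0.0975, 0.177 and 0.416). So did the chemokine call without M replicate 1 (0.0733) or 2 (0.0756) and the G2/M call without M replicate 2 (0.0561). In all, the chemokine call was lost in 14 of 29 alternatives, with the median turning to -0.06 at a mean FPKM of at least 5. The immediate-early call was lost in 11, the G2/M call in 4 and the class I call in 2. Over all alternatives these 4 lists ran from 6.27e-05 to 0.565, 0.000594 to 0.196, 9.63e-05 to 0.225 and 0.00141 to 0.416. The limma fit of the design fixed in advance lost the chemokine and immediate-early calls.

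The other lists were not called between M and ET. Members higher and lower in M numbered 3 and 4 of 16 for the nitric oxide, prostaglandin and itaconate enzymes, 4 and 2 of 32 for glycolysis, 3 and 0 of 18 for heat shock and 3 and 0 of 36 for ribosome biogenesis. They numbered 0 and 3 of 15 for the inflammasome, 1 and 3 of 26 for autophagy, 2 and 2 of 20 for LXR targets, 2 and 1 of 20 for other receptors and 1 and 4 of 17 for macrophage identity. No member of the mitochondrially encoded, ribosomal protein or osteoclast lists passed (camera Benjamini-Hochberg adjusted p = 0.512, 0.512 and 0.725). With the GC offset the mitochondrially encoded list was called, lower in M (camera Benjamini-Hochberg adjusted p = 0.0233). In 4 lists 1 member passed, chosen here for that reason after the values were seen: Myd88 of TLR4 signalling (log2 change 0.14), Trem2 of alternative activation (-0.48), Btg2 of the p53 targets (0.39) and Uqcrq of the respiratory chain (-0.19). Adjusted over the list alone, Myd88 and Uqcrq did not pass. Camera gave these 4 lists Benjamini-Hochberg adjusted p = 0.217, 0.0935, 0.963 and 0.0644. The LXR list had a median of 0.01, a mean of -0.06 and a camera direction of down. Within it Abca1 was higher in M (log2 change 1.20) and the other sterol exporter Abcg1 lower (-0.67). Camera adjusted p (Benjamini-Hochberg) was 0.597 for the enzymes, 0.0935 for glycolysis, 0.0709 for heat shock, 0.123 for the inflammasome, 0.0793 for autophagy, 0.725 for LXR targets, 0.725 for other receptors, 0.102 for ribosome biogenesis and 0.0768 for macrophage identity. Of 29 alternatives, 12 called glycolysis (adjusted p 0.00499 to 0.416), 13 heat shock, 14 the respiratory chain, 5 macrophage identity, 4 ribosome biogenesis and 3 autophagy (0.00262 to 0.226; Benjamini-Hochberg). A single library moved some of these past the threshold (camera, Benjamini-Hochberg). Heat shock passed without ET replicate 3 (0.0281) or M replicate 1 (0.0426), in a range of 0.0132 to 0.343 over the alternatives. The respiratory chain passed without ET replicate 2 (0.0139), ET replicate 3 (0.0119) or M replicate 2 (0.0413), in a range of 0.0089 to 0.683. Macrophage identity passed without M replicate 1 (0.0341; range 0.0215 to 0.411), and ribosomal proteins and ribosome biogenesis without ET replicate 3 (0.0486 each; ranges 0.0486 to 0.894 and 0.0116 to 0.412).

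The last comparison asked whether the genes that responded in the treated mean lay closer to Normal or farther from it in M than in ET. Response genes were the 1221 risen and 585 fallen genes with at least a 2-fold change in that mean. Farther from Normal in M were 238 of them, 182 risen genes that were higher in M, such as Ccr7, Lif and Il6, and 56 fallen genes that were lower. Closer to Normal in M were 122, namely 95 risen genes that were lower in M, such as Hmox1, Ptgr1 and Tnf, and 27 fallen genes that were higher. By the column names the extract group was thus the farther in those 238 genes, and by the library names it was the closer. Across the 1806 genes, which are not independent replicates, the difference rose with the response with a slope of 0.0307, r = 0.241 and rho = 0.175. With no minimum change rho was 0.0350. With the response defined from ET against Normal, which shares the ET libraries, rho was 0.0633, the risen median 0.00113, the fallen median 0.02 and the counts 220 farther and 156 closer. That sharing lowers the correlation by construction. Over all genes the covariance for this pair of comparisons was 0.0300, against -0.0120 in simulated unchanged groups. Their r of -0.498 belongs to groups without any real change, so it is no baseline for the observed r of 0.0804. The risen set had a median log2 difference of 0.03 (camera Benjamini-Hochberg adjusted p = 0.0407, and adjusted p = 0.122 with an estimated correlation). With a library left out that median ran from 0.00947 (ET replicate 3) to 0.0353 (M replicate 3). The fallen set had a median of -0.03 (camera Benjamini-Hochberg adjusted p = 0.0545, and 0.122 with an estimated correlation). The count of closer genes was 74 without ET replicate 2 and 74 without M replicate 3.

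**Figure D3:**
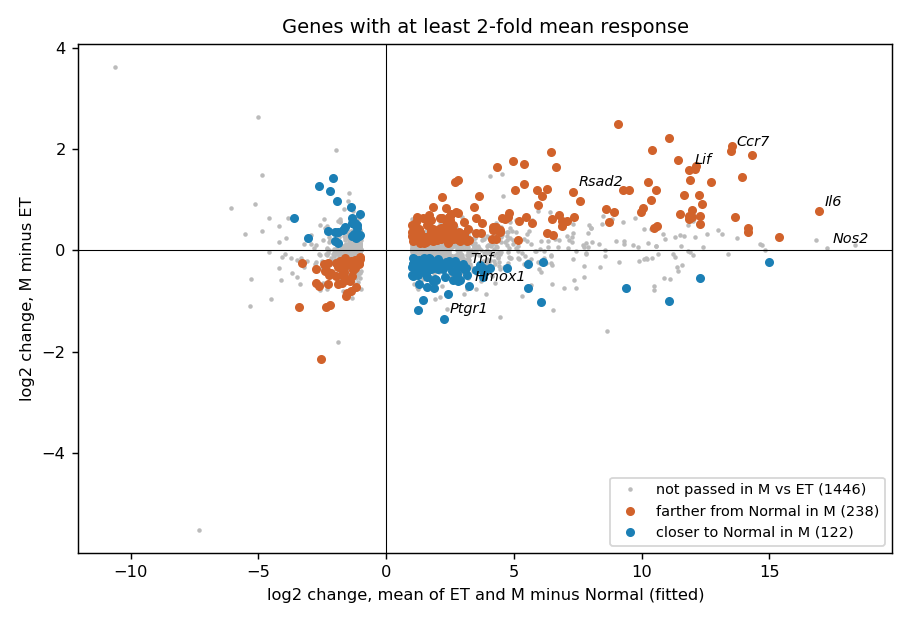
Each point is 1 of 1806 response genes, with the fitted log2 change of the treated mean against Normal on the horizontal axis and the log2 change of M minus ET on the vertical axis; fitted responses of genes with 0 counts in Normal depend on the model and are not fold estimates. Orange points were farther from Normal in M (238), blue points closer (122), and grey points did not pass the edgeR quasi-likelihood test between M and ET.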

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

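The tests of a stronger response, of GC and length offsets, of B-lymphocyte RNA and of fibroblast RNA in this part were chosen only after the results were seen. A set of 13 genes was called in both comparisons with Normal but in opposite directions, so that a difference between M and ET follows from how they were chosen. Log2 changes of M minus ET were -1.09 for Slc40a1, -0.77 for Blvrb, -0.72 for Cat, -0.38 for Tnfaip2, -0.37 for Kcnn4, -0.28 for Cyb5a, -0.25 for Nek6 and -0.21 for Prdx6. They were 0.92 for Idi1, 0.65 for Pcmtd1, 0.42 for Stk38l, 0.42 for Hsp90b1 and 0.28 for Ccdc50. Slc40a1 stood at 11.9 CPM in Normal, 16.4 in ET and 7.67 in M, and Idi1 at 168.8, 112 and 212.

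The difference between M and ET has the same size under both readings of the labels, but its direction is not settled. An exchange of the columns of the LPS and LPS+Extract groups keeps every size and turns every sign by construction, for the 1048 called genes as for all others, so that test is void and cannot tell which reading is right. A candidate explanation that the M libraries hold a stronger response of the same kind and nothing else did not hold: of the genes called both in the treated mean and between M and ET, 510 moved farther from Normal in M and 408 (44.4%) moved back toward it. A trend on transcript GC content may account for part of the gene calls, since 79.1% of them were still called with the offset, under the 80% set as the bound, and this stays open. With that offset 0 called genes reversed and 205 others were newly called. Log2 changes of all genes moved by a median of 0.039, against a median size of 0.28 among called genes. For the lists a GC trend was excluded, as 7 of 7 were still called. With the length offset 86.4% of genes and 6 of 7 lists were still called, and 166 genes were newly called. A trend on transcript length therefore does not account for most calls, but it stays open for the genes that lost theirs. The bounds were set after the results were seen. The list lost with the length offset was the metal response (camera with an estimated correlation, Benjamini-Hochberg adjusted p = 0.0542). Its median went from -0.11 to -0.13, so the loss does not show that length explains it.

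Ighm stood at 468 CPM in Normal and 51.3 in ET, and Lum at 0 counts in Normal and 13.1 CPM in M. B-lymphocyte RNA in the Normal libraries could give the first, but Cd79b, the most abundant there of Cd79a, Cd79b and Igkc, reached 0.0837% of the Ighm level. Fibroblast RNA in the treated libraries could give the other, but Col1a1, Col1a2 and Col3a1 together reached 5.13% of the Lum level in ET (8.13 CPM), the higher share of the treated groups. Other fibroblast markers, all below the filter, went both ways. Dcn went from 0 counts to 1.53 CPM in ET and 3.02 in M, and Fap and Acta2 were also higher. Pdgfrb, Col1a2 and Col3a1 were lower in both treated groups. At the bounds set both explanations were excluded, for fibroblast RNA on the collagens alone. The cause of either change was not tested further.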

How the results depend on the processing

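Alternatives using limma as designed, DESeq2, other count factors, filterByExpr, offsets and protein-coding genes were chosen after the data were seen. The cause of each change below was not tested, except that stricter thresholds call fewer genes by construction. Genes higher and lower in M than ET numbered 573 and 475, against 339 and 421 with limma at a pseudocount of 0.1, 304 and 392 at 0.01, 345 and 270 with no filter, 895 and 787 with DESeq2, 41 and 13 at a log2 change of at least 1, 215 and 171 at adjusted p under 0.01, 508 and 414 with a replicate block, and 475 and 573 with exchanged labels. Leaving out each library gave 265.0 to 1121 higher and 244 to 707 lower. Deviations of the same replicate number correlated weakly between ET and M (r = 0.0756, 0.0373 and 0.0309), above all pairs of different numbers (-0.0571 to 0.0233). With Normal, same-number pairs ran from -0.0503 to 0.00985, where different numbers reached 0.0861. A log2 change of at least 1 left 1243 and 605 genes for ET with Normal, 1226 and 609 for M with Normal, and 1221 and 585 for the treated mean. Response genes farther and closer numbered 238 and 122, against 122 and 238 with exchanged labels, 510 and 408 with no minimum change, 145 and 50 with a response of at least 2, 81 closer with limma at 0.01, 187 closer with DESeq2, and 161 to 256 farther and 74 to 167 closer with a library left out. Test directions reversed for 3 lists. For the mitochondrially encoded genes in M with ET the median also turned, from 0.04 to -0.10 with the GC offset. That list, not called otherwise, was called there (camera Benjamini-Hochberg adjusted p = 0.0233). For the nitric oxide, prostaglandin and itaconate enzymes in M with Normal only the camera direction turned, from up to down with limma and median-of-ratios scaling (median -0.16 and -0.15). For ribosome biogenesis in M with Normal camera pointed down and fry up, on the same median of 0.00315 (Benjamini-Hochberg adjusted p = 0.813 and 0.0128). Over the 29 alternatives run on lists between M and ET, which do not include the exchanged labels, 807 list results kept their direction and side of the threshold, 35 lost a call, 55 gained one and 1 reversed. For the treated mean 788 kept theirs, 21 lost a call and 58 gained one. Among results for genes that the naming rule covers, 2056 between M and ET kept theirs, 17 gained a call and 46 lost one. These lost calls are in large part of genes whose change between M and ET the text does not print. For ET with Normal 3040 kept theirs and 1 lost a call, and for M with Normal all 2849 kept theirs. The median change of all genes for ET with Normal was -0.018, against -0.104 with limma on rescaled FPKM, -0.0798 with limma on log2 FPKM and -0.0955 with total counts only.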

Other observations

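Among KEGG terms of all genes called higher in M than ET, Influenza A held 29 of 117 tested members (hypergeometric, Benjamini-Hochberg adjusted p = 1.95e-07), Steroid biosynthesis 9 of 15 (1.66e-05) and Cytokine-cytokine receptor interaction 22 of 94 (1.88e-05). Among genes lower in M, Mineral absorption held 8 of 23 (0.00482), Lysosome 18 of 108 (0.00482) and Ferroptosis 9 of 34 (0.00849). Genes risen at least 2-fold in the treated mean were enriched for Cytokine-cytokine receptor interaction, 52 of 94 (4.49e-21), and genes fallen at least 2-fold for PPAR signaling, 10 of 39 (0.0026). A total of 289 terms were tested, and only some of those called are named. Called were 32 terms higher and 7 lower in M, and 60 risen and 1 fallen in the treated mean. The hypergeometric test takes genes as independent, so its p can be too small where genes move together. The lysosome list, with an estimated correlation of 0.406, lost its camera call between M and ET.

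Markers of other cells were few. Of 18 lymphocyte markers 2 were tested, of 17 fibroblast markers 1, of 16 epithelial and endothelial markers 2, of 14 erythroid and platelet markers 1, and of 17 granulocyte markers 2. In the treated mean, 1 lymphocyte, 1 epithelial and endothelial and 1 granulocyte marker rose and 1 of each fell, while 1 fibroblast and 1 erythroid marker rose. S100a8 went from 0.017 CPM in Normal to 32.1 in ET and 34.0 in M, and Csf3r from 12.7 to 1.56 and 0.98.

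All list splits with an estimated correlation were chosen after the results were seen. With 3 against 3 libraries there are 10 splits, so that the share of splits as large as the real one cannot go under 0.05. Called genes numbered 8103 for ET with Normal (highest other 0), 8079 for M with Normal (0) and 1048 for M with ET (1), each reached by 1 split, the real one. Lists called with an estimated correlation numbered 9, 9 and 7 (highest other 0 in each), each reached by 1 split. With the preset correlation they numbered 24, 22 and 15 (highest other 21, 19 and 12), each reached by 1 split. Response genes farther in M numbered 238 (highest other 0; 1 split). For the treated mean, with 84 splits, chance was excluded for 8154 called genes in a fit of 2 groups (highest other 5) and for 4 lists with an estimated correlation (highest other 1). That fit calls 4 lists where the fit of 3 groups called 11, so the splits say nothing of the other calls. The 23 lists called with the preset correlation were reached by 14 of 84 splits, so chance was not excluded for that count. Each of the other splits among these held 2 Normal libraries or none in its group of 3. Such splits still carried part of the real contrast, which limits what this count can show.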
